A study of Homo sapiens with 12 samples.

How the data were processed

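Poly(A)-selected RNA was sequenced from WI-38 cells, an established line of human fetal lung fibroblasts, per the labels. The cells had received lentivirus carrying a control short hairpin RNA or 1 of 2 hairpins directed at MIR222HG, called sh1 and sh2 here. They were collected either quiescent, in medium with 0.1% serum and puromycin, or after 6 h in 10% serum, per the labels' protocols. This made 6 groups of 2 libraries and 12 libraries in all. The 2 libraries of a group are described only as biological replicates, and no date, batch or pairing of cultures is given. Libraries came from a stranded mRNA kit and were sequenced in pooled, paired-end runs, per the labels' protocols.

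The deposited values are whole-number counts of reads per Ensembl gene, 1 table per library, with no normalisation by the authors. Reads were aligned to GRCh38 with HISAT2 and counted with HTSeq, per the submitters' processing notes. Tool versions, the gene annotation, the counting mode and the strand setting are not given in the sources used here. A gene that overlaps another, lies antisense to one or has a near-identical copy therefore has an uncertain count. The 5 summary counts that HTSeq adds to each table were left out of totals and tests. All 58735 of 58735 gene identifiers matched the GENCODE release 29 annotation, which supplied symbols, positions, exons and untranslated regions.

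Assigned counts per library ran from 21128703 to 27979666, and 76.4% to 81.3% of the counted reads of a library were assigned to a gene. A gene with no count in a group could still be present at up to 3 counts over the group, and folds against such a group are given as lower bounds from that floor. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. In replicate pairs the spread exceeded counting error (chi-square per gene between 8.34 and 15.6), so the tests rest on spread among libraries, and depth limits only the rarest transcripts.

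Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 15361 genes that passed filterByExpr by group were tested. Libraries were scaled by TMM, the trimmed mean of M values, with factors between 0.887 and 1.141. A negative binomial model with 1 coefficient per group was fitted to all 12 libraries together, which left 6 residual degrees of freedom per gene, and every comparison used the quasi-likelihood F test, two-sided. P-values were adjusted over the genes tested in a comparison by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. The biological coefficient of variation was 8.78%. Levels are in CPM, counts scaled to the TMM-adjusted library size and computed here, as mean ± SD with n = 2 libraries, and log2 fold changes are given ± their standard error.

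There were 12 comparisons, of which 4 were main ones: the mean of the hairpin groups against control in quiescence, the same at 6 h, 6 h against quiescence in control, and the difference between the serum response of the hairpin arms and that of the control arm. The others were each hairpin against control in each state, the serum response in each hairpin arm, and sh2 against sh1 in each state. The number of genes changed alike by both hairpins was set beside the number for independent lists and beside 20 simulated draws in which unchanged hairpin groups were compared with the same control libraries. The size of the serum response was compared by the slope of an orthogonal regression of each hairpin arm's log2 fold changes on those of control, over genes changed at least 2-fold on average over the 3 arms.

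A set of 26 gene lists was tested in the 4 main comparisons with camera from limma 3.58.1, on the preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists hold immediate early and growth factor response genes, SRF and MRTF cytoskeletal genes, YAP and TEAD targets, G1/S and DNA replication genes, G2/M and mitotic genes, G1 regulators, p53 target genes, FOXO targets and genes of serum-starved cells, MYC-linked ribosome biogenesis genes, cytosolic ribosomal proteins, cholesterol synthesis and uptake genes, interferon-stimulated genes, inflammatory and NF-kB genes, extracellular matrix genes, TGF-beta and BMP response genes, amino acid response and unfolded protein genes, hypoxia and glycolysis genes, reported targets of miR-221 and miR-222, host genes and other long noncoding RNAs, mitochondrially encoded mRNAs, and markers of fibroblasts, epithelium, endothelium, immune cells, smooth muscle with pericytes, and senescence. Numbers of changed members are those of edgeR over all genes tested unless another tool is named, and beside them adjusted over the list alone.

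The comparisons, lists, tests and most alternatives were chosen before the data were examined. So was the rule for the genes named. MIR222HG is given first in every library. In each main comparison the rule takes, among genes with an approved symbol, a mean of at least 2 CPM over the 12 libraries and an adjusted p under 0.05, the 10 with the largest and the 10 with the smallest log2 fold change. For the hairpins against control a gene had to pass with each hairpin separately and with the same sign. For the serum response and its difference between arms, every library of one group had to lie beyond every library of the other, or both hairpins had to differ from control in the same direction. In each list the rule takes up to 4 members with the lowest adjusted p, in each remaining comparison the 3 largest and 3 smallest changes, and a few single genes, DNM3OS and ILF2 among them, wherever tested. The text describes some of the genes so chosen.

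The alternatives were relative log expression size factors, library totals alone, no filter beyond 1 read in 1 library, a stricter filter of 2 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, a fit on only the groups compared, each library left out in turn, and other gene sets and ordinary least squares for the slopes. A correction for transcript GC content, comparisons that share no library, the serum response of the other hairpin and an overlap without genes that hold an arm's word were added after seeing the data. When 1 library is left out, its partner is assumed to vary like the libraries of the other groups. Seven-base words were searched in the annotated 3' untranslated regions of 12646 of the genes tested, and each of 16243 words was ranked by how far the genes holding it were shifted in a hairpin comparison. The hairpin sequences are not given in the sources used here, so the words rest on expression alone and could not be compared with them. The fits were tested on simulated counts in which 200 of the 15361 genes were changed: for the hairpins against control in quiescence, 56.7%, 70.1% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 10% of calls were false. For the difference in serum response the shares were 32.8%, 59.7% and 81.8%, with 6.5% false. Y-linked genes and XIST were not named, and no sample was left out.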

Results

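RNA levels were measured in WI-38 human lung fibroblasts that carried a control hairpin, sh1 or sh2, each either quiescent in low serum or after 6 h in 10% serum. Each of the 6 groups had 2 libraries. Assigned counts per library were 26135591 and 27979666 in quiescent control, 26353715 and 25537691 in quiescent sh1 and 22779295 and 24924430 in quiescent sh2. At 6 h they were 23066399 and 24069575 in control, 26562310 and 24547791 in sh1 and 23110583 and 21128703 in sh2. A total of 15361 genes was tested. The first principal component held 74.7% of the variance and the second 7.2%. All 12 libraries correlated best with the other library of their own group.

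MIR222HG, the host transcript of the miR-221 and miR-222 genes and the stated target of both hairpins, was not lower in the libraries labelled as hairpin. The gene (ENSG00000270069) is a long intergenic noncoding RNA on the minus strand of chromosome X, from 45745211 to 45770274 on GRCh38. In quiescence its level was 15.0 ± 1.09 CPM in control, 24.5 ± 0.785 CPM in sh1 and 26.0 ± 2.24 CPM in sh2 (SD, n = 2 libraries each). The single libraries were at 14.2 and 15.8 CPM in control, 25 and 23.9 CPM in sh1, and 24.4 and 27.5 CPM in sh2. The mean of the hairpin groups was higher than control by 0.75 ± 0.09 on the log2 scale, which is 1.68-fold (adjusted p = 0.000139), with each of the 4 hairpin libraries above both control libraries. At 6 h the levels were 32.5 ± 2.51 CPM in control (30.8 and 34.3), 31.1 ± 1.17 CPM in sh1 (31.9 and 30.2) and 31.6 ± 1.86 CPM in sh2 (32.9 and 30.2). The log2 difference of -0.06 ± 0.09 was not past the test (adjusted p = 0.786). Serum raised MIR222HG by 1.12 ± 0.11 in control (adjusted p = 3.61e-07), by 0.34 ± 0.10 in sh1 (adjusted p = 0.0102) and by 0.28 ± 0.10 in sh2 (adjusted p = 0.0351). With library totals as the only scaling the MIR222HG rise was 0.08 in sh1 and 0.09 in sh2 (adjusted p = 0.559 and 0.528) but 0.83 in control (adjusted p = 1.28e-05). The sh1 call was also lost without quiescent replicate 2 or 6 h replicate 1 of sh1 (0.0714 and 0.0682), and the sh2 call without replicate 1 of sh2 in quiescence or at 6 h (0.226 and 0.178). Because the target was not lower, the groups are named below by their labels, and no direction is read as an effect of less MIR222HG.

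**Figure D1:**
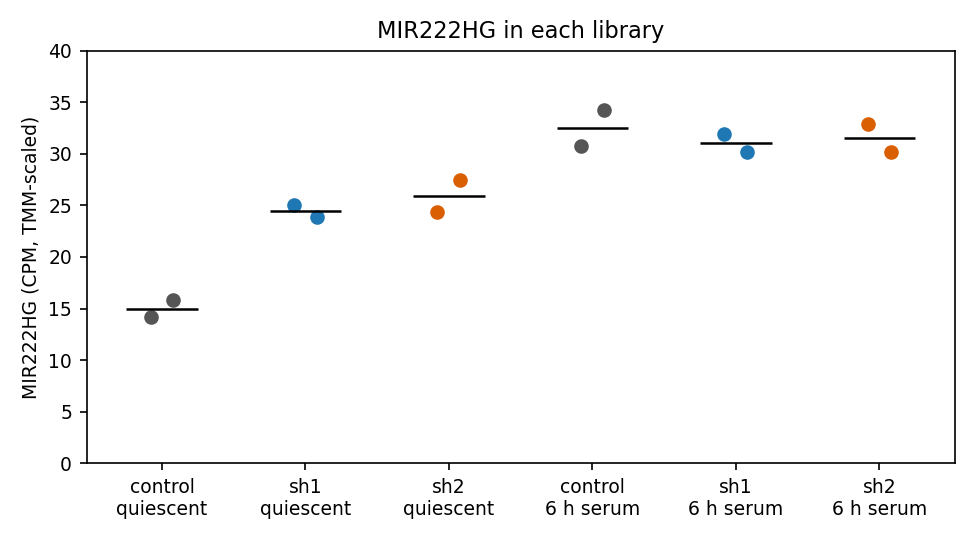
MIR222HG level in CPM, counts scaled to library size (linear axis from 0), in the 6 groups, with 1 dot per library and bars at the group means. The quiescent control bar stands at 15.0 CPM, below the quiescent sh1 and sh2 bars at 24.5 and 26.0 CPM, and the bars at 6 h stand at 32.5, 31.1 and 31.6 CPM.

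The first comparison asks how quiescent cells with a MIR222HG hairpin differ from quiescent control cells. SFRP1, a secreted antagonist of Wnt signalling, rose from 561 ± 29.2 CPM in control to 1610 ± 101 CPM in sh1 and 1710 ± 119 CPM in sh2 (SD, n = 2 each), a log2 difference of 1.57 ± 0.09 (adjusted p = 2.87e-07). The largest rise was that of SERPINB7, an inhibitor of serine proteases, by 2.86 ± 0.21 (adjusted p = 1.32e-06; 1.18, 4.41 and 16.8 CPM in control, sh1 and sh2). The complement component C7 fell by 2.32 ± 0.15 (adjusted p = 4.44e-07), from 196 ± 14.0 CPM to 50.5 ± 10.8 CPM in sh1 and 30.3 ± 2.33 CPM in sh2. VCAM1, an adhesion molecule for leukocytes, fell by 2.05 ± 0.12 (adjusted p = 2.87e-07; 147, 55.0 and 22.8 CPM). In all, 2183 genes differed, 1003 higher and 1180 lower in the hairpin libraries, and 293 of them by at least 2-fold. Other large rises were those of NPTX1 (1.81), IL13RA2 (1.66) and ITGA10 (1.55), and other large decreases those of SHISA3 (-1.77), COL14A1 (-1.72) and the secreted proteases ADAMTS8 (-1.68) and ADAMTS1 (-1.67). XDH (1.89) and PCK2 (-1.74) were no longer past the test without control replicate 1 of the quiescent state (adjusted p = 0.0867 and 0.0788). Without that library 803 genes were past the test, of which 777 were among the 2183. The 3' untranslated regions of SLC14A1 (1.67) and ADAMTS1 hold the 7-base word AGGTGTA, whose holders were lower as a set in the sh1 libraries, and that of PTHLH (-2.16) holds GTTTATC, whose holders were lower as a set in the sh2 libraries. These words, called the sh1 word and the sh2 word below, were found from the expression values. The hairpin sequences are not given in the sources used here, so neither word could be compared with them.

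In the quiescent state the extracellular matrix genes were lower in the hairpin libraries. Of 33 members tested, 22 fell, 11 did not pass and none rose in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05 (23 fell adjusted over the list alone, camera adjusted p = 1.14e-12, adjusted p = 0.346 with an estimated correlation). DCN and LUM, proteoglycans that bind collagen fibrils, fell by 0.80 ± 0.09 and by 0.77 ± 0.10 (adjusted p = 4.85e-05 and 0.000179), and DCN went from 11400 CPM in control to 6680 CPM in sh1 and 6420 CPM in sh2. The fibril-associated collagen COL12A1 fell by 0.57 ± 0.08 (adjusted p = 0.000331). Among 28 amino acid response and unfolded protein genes, 16 fell and none rose, again by any of these counts (18 fell adjusted over the list alone, camera adjusted p = 5.87e-08, adjusted p = 0.346 with an estimated correlation). In this list VLDLR, a lipoprotein receptor, fell by 0.68 ± 0.12 (adjusted p = 0.00224), while SLC3A2 (-0.65) and SLC7A5 (-1.37), the chains of an amino acid transporter, were not past the test without control replicate 1 (adjusted p = 0.0638 and 0.106). Of 29 interferon-stimulated genes, 13 fell and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 2.25e-06, adjusted p = 0.346 with an estimated correlation). XAF1, an interferon-induced promoter of apoptosis, fell by 1.62 ± 0.21 (adjusted p = 0.000198; 9.09, 4.8 and 1.8 CPM).

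Smaller shares of 4 further lists changed in quiescence. Of 22 TGF-beta and BMP response genes, 4 fell and none rose in edgeR, where 2 rose in DESeq2, 1 in limma-voom and 2 at an unadjusted p under 0.05 (9 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.000421, adjusted p = 0.346 with an estimated correlation). GREM1, a secreted BMP antagonist, fell by 1.18 ± 0.10 (adjusted p = 2.37e-06; 1170, 681 and 389 CPM), and ID3, a BMP-induced inhibitor of differentiation factors, fell by 1.31 ± 0.12 (adjusted p = 1.12e-05). Of 13 smooth muscle and pericyte markers, 6 fell and none rose in any of the 3 tools or unadjusted (7 fell adjusted over the list alone, camera adjusted p = 7.84e-05, adjusted p = 0.346 with an estimated correlation), and MCAM, an adhesion molecule of pericytes, fell by 0.76 ± 0.09 (adjusted p = 9.14e-05). Of 24 cholesterol synthesis and uptake genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 7.27e-05, adjusted p = 0.346 with an estimated correlation). FDPS, an enzyme of the mevalonate route, rose by 0.49 ± 0.07 (adjusted p = 0.000344; 161, 186 and 276 CPM). The 13 mitochondrially encoded mRNAs leaned upward, with 2 that rose (8 adjusted over the list alone, camera adjusted p = 0.000464, adjusted p = 0.428 with an estimated correlation). The 2 that passed over all genes, MT-ND3 and MT-ND4L, had log2 differences of 0.23 and 0.24 and were not past the test without control replicate 1 (adjusted p = 0.391 and 0.402), nor without 8 of the other libraries taken singly.

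In quiescence 6 more lists were past camera's test but lost the call with an estimated correlation and without at least 1 library. The SRF and MRTF cytoskeletal genes had 6 of 20 members lower and none higher in any of the 3 tools, with 1 higher at an unadjusted p under 0.05 (8 lower adjusted over the list alone, camera adjusted p = 0.00636, adjusted p = 0.517 with an estimated correlation), and ACTG2, a smooth muscle actin, fell by 0.81 ± 0.10. The fibroblast markers had 7 of 18 lower and 2 higher (8 and 2 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.368 with an estimated correlation), with S100A4, a calcium-binding protein, up by 0.95 ± 0.08 from 46.3 CPM to 98.7 and 80.7 CPM. The host genes and other long noncoding RNAs had 5 of 35 higher (5 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.428 with an estimated correlation), with LINC-PINT up by 1.41 ± 0.18. Without control replicate 1 the adjusted p of these lists was 0.278, 0.0689 and 0.316. The ribosome biogenesis genes had 5 of 31 higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00384, adjusted p = 0.517 with an estimated correlation). RRS1 was up by 0.93 ± 0.13. The p53 target genes had 4 of 25 higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.346 with an estimated correlation), with the cyclin CCNG1 up by 0.60 ± 0.09. The cytosolic ribosomal proteins had 2 of 52 higher (2 adjusted over the list alone, camera adjusted p = 0.0306, adjusted p = 0.759 with an estimated correlation). Without control replicate 2 these 3 values were 0.184, 0.0776 and 0.954. The fibroblast value was 0.0634 without sh2 replicate 2, the p53 value 0.0524 without sh1 replicate 2, and the ribosomal protein value 0.135 without sh2 replicate 1.

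No cell-cycle list was past camera's test in quiescence with all libraries, where 2183 of all 15361 genes tested differed. None of 27 G2/M and mitotic genes passed edgeR's test, 0 with an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom (camera adjusted p = 0.16, but 0.0101 without sh1 replicate 1 and 0.00931 without sh2 replicate 1). Of the others, 3 of 31 G1/S and DNA replication genes did (camera adjusted p = 0.814), and 3 of 21 G1 regulators rose while 3 fell (camera adjusted p = 0.787). CDKN2B, an inhibitor of the G1 cyclin-dependent kinases, rose by 0.68 ± 0.10 (adjusted p = 0.000385; 30.5, 38.6 and 61.8 CPM). Of 25 reported targets of miR-221 and miR-222, 3 rose and 3 fell (camera adjusted p = 0.857), and SOCS3, an inhibitor of cytokine signalling, fell by 0.69 ± 0.09. The immediate early and growth factor response genes (6 of 32 higher and 2 lower, 8 and 2 adjusted over the list alone) and the hypoxia and glycolysis genes (1 of 25 higher and 6 lower, 1 and 9 adjusted over the list alone) were just short of the test, at a camera adjusted p of 0.05 each. Both moved past it when any of several single libraries was left out. The immediate early value was 0.000457 without control replicate 1, 0.0063 without sh1 replicate 2 and 0.000823 without sh2 replicate 2, and the hypoxia value 0.0306 without sh1 replicate 1 and 0.01 without sh2 replicate 1. Also short of the test were the FOXO targets (3 of 27 higher, 6 lower, camera adjusted p = 0.787), the YAP and TEAD targets (2 of 16 higher, 3 lower, 0.787) and the inflammatory genes (2 of 28 higher, 1 lower, 0.129). So were the senescence markers (2 of 18 higher, 4 lower, 0.857), epithelial markers (1 of 5 higher, 0.201) and endothelial markers (1 of 5 lower, 0.0724, and 0.0475 without control replicate 2). Only 2 immune cell markers reached the level needed for a test, and neither passed in edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05. DNM3OS (-0.18) and ILF2 (0.05) did not pass either.

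The next comparison asks the same of cells taken 6 h into serum. CTHRC1, a secreted protein of matrix remodelling, fell by 1.69 ± 0.07 (adjusted p = 7.81e-09), from 320 ± 36.8 CPM in control to 70.9 ± 1.48 CPM in sh1 and 139 ± 1.59 CPM in sh2 (SD, n = 2 each). C7 again fell, by 2.24 ± 0.15 (adjusted p = 8.04e-07; 159, 41.4 and 27.3 CPM), and so did COL14A1, by 1.67 ± 0.11 (adjusted p = 6.72e-07). SFRP1 was higher by 1.25 ± 0.09 (adjusted p = 1.36e-06; 631, 1320 and 1700 CPM) and SERPINB7 by 1.96 ± 0.19 (adjusted p = 1.66e-05). MAMDC2, a proteoglycan, was higher by 1.75 ± 0.17 (adjusted p = 1.66e-05; 6.79, 17.0 and 30.8 CPM). The test was passed by 1099 genes, 268 higher and 831 lower in the hairpin libraries, 151 of them by at least 2-fold. The share that was higher, 24.4%, rose to 49.1% (543 higher, 564 lower) when libraries were scaled by their totals alone. Leaving out control replicate 1 or 2 of the 6 h state left 420 genes past the test in either case, of which 406 and 395 were among the 1099, and leaving out sh1 replicate 2 left 731. COL4A5 (-1.82) holds the sh2 word, SCD5 (-1.62) both words, and GNG4 (-1.55) and ADAMTS19 (-1.53) the sh1 word. FLRT2 (0.99), which was higher, holds the sh2 word as well. YPEL3 (1.15) and FLRT2 were not past the test without control replicate 1 (adjusted p = 0.115 and 0.135).

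Inflammatory and NF-kB genes were lower in the hairpin libraries at 6 h. Of 28 members, 8 fell, 20 did not pass and none rose in any of the 3 tools or unadjusted (15 fell adjusted over the list alone, camera adjusted p = 9.3e-09, adjusted p = 0.016 with an estimated correlation). With a block for the replicate number added to the estimated correlation, this list was no longer past the test. The monocyte chemokine CCL2 fell by 1.13 ± 0.10 (adjusted p = 9.46e-06; 52.7, 26.5 and 22.0 CPM), TNFAIP3, a feedback inhibitor of NF-kB, by 0.60 ± 0.09 (adjusted p = 0.000702), and VCAM1 by 1.25 ± 0.18 (adjusted p = 0.000619). The cytokine IL11 was at 1800 CPM in control, 1050 CPM in sh1 and 948 CPM in sh2 (log2 difference -0.85 ± 0.17, adjusted p = 0.00723), and was not past the test without control replicate 1 or 2 (adjusted p = 0.0844 and 0.0527). Extracellular matrix genes were again lower, 9 of 33 with none higher by the same counts (18 lower adjusted over the list alone, camera adjusted p = 5.7e-08, adjusted p = 0.548 with an estimated correlation). DCN fell by 0.84 ± 0.09 (adjusted p = 3.67e-05) and LUM by 0.79 ± 0.10 (adjusted p = 0.00018).

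In several other lists a minority of members differed at 6 h. Of 32 immediate early and growth factor response genes, 4 fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.556 with an estimated correlation, and 0.0797 without control replicate 1). EGR1, a transcription factor of the first wave after serum, fell by 1.44 ± 0.10 (adjusted p = 7.53e-07; 16.9, 8.86 and 4.32 CPM), and HBEGF, a ligand of the EGF receptor, by 0.82 ± 0.13 (adjusted p = 0.00161). Of 28 amino acid response and unfolded protein genes, 5 fell (7 adjusted over the list alone, camera adjusted p = 0.00151, adjusted p = 0.548 with an estimated correlation), and the co-chaperone DNAJB9 fell by 0.74 ± 0.09. Of 13 smooth muscle and pericyte markers, 3 fell (7 adjusted over the list alone, camera adjusted p = 0.000154, adjusted p = 0.513 with an estimated correlation). Of 29 interferon-stimulated genes, 2 fell (9 adjusted over the list alone, camera adjusted p = 0.000528, adjusted p = 0.548 with an estimated correlation, and 0.0545 without control replicate 2). Of 18 senescence markers, 5 fell (8 adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.47 with an estimated correlation, and 0.0545 without control replicate 2). Of 25 p53 targets, 2 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.000889, upward, adjusted p = 0.431 with an estimated correlation), with CCNG1 up by 0.58 ± 0.09. The 52 ribosomal proteins leaned upward as a set (camera adjusted p = 7.9e-05, adjusted p = 0.548 with an estimated correlation), though RPS2 was the sole member to pass singly in edgeR, with 1 member in DESeq2, 1 in limma-voom, 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The RPS2 call was lost without any 1 of 6 libraries, with adjusted p between 0.0593 and 0.378.

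The calls of the remaining lists at 6 h hung on single libraries. SRF and MRTF cytoskeletal genes (2 of 20 lower, 4 adjusted over the list alone, camera adjusted p = 0.00968, adjusted p = 0.591 with an estimated correlation) were at 0.118 without control replicate 1. Fibroblast markers (5 of 18 lower and 1 higher, 6 and 1 adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.524 with an estimated correlation) were at 0.0699 without control replicate 1, 0.0638 without sh1 replicate 2 and 0.0506 without sh2 replicate 2. YAP and TEAD targets (4 of 16 lower and 1 higher, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0496, adjusted p = 0.67 with an estimated correlation) were less stable still. Their value rose to 0.0935 and 0.071 without control replicates 1 and 2, and to 0.184 without sh1 replicate 2 and 0.199 without sh2 replicate 2. Hypoxia and glycolysis genes (4 of 25 lower, 7 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0466, adjusted p = 0.548 with an estimated correlation) were no firmer. Their value rose to 0.106 and 0.0545 without control replicates 1 and 2, 0.101 without sh1 replicate 2, 0.0925 without sh2 replicate 1 and 0.0532 without quiescent control replicate 1. In other lists INSIG1, which holds back transcription of cholesterol synthesis genes, fell by 1.43 ± 0.10 (adjusted p = 7.79e-07; 355, 91.7 and 190 CPM). ODC1, the first enzyme of polyamine synthesis, fell by 0.81 ± 0.10 (adjusted p = 0.000101; 1140, 772 and 552 CPM). The other 12 lists with enough members were not past the test (camera adjusted p between 0.106 and 0.718). None of 27 mitotic genes passed edgeR's test, 0 with an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom, and as a set they were past camera's test only without control replicate 2 (0.0083), sh1 replicate 1 (0.00547) or sh2 replicate 1 (0.000253) of the 6 h state. DNM3OS differed by -0.48 ± 0.13 (adjusted p = 0.0358), a call lost without any 1 of the 6 libraries taken at 6 h (adjusted p between 0.0562 and 0.346) and with library totals.

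**Figure D2:**
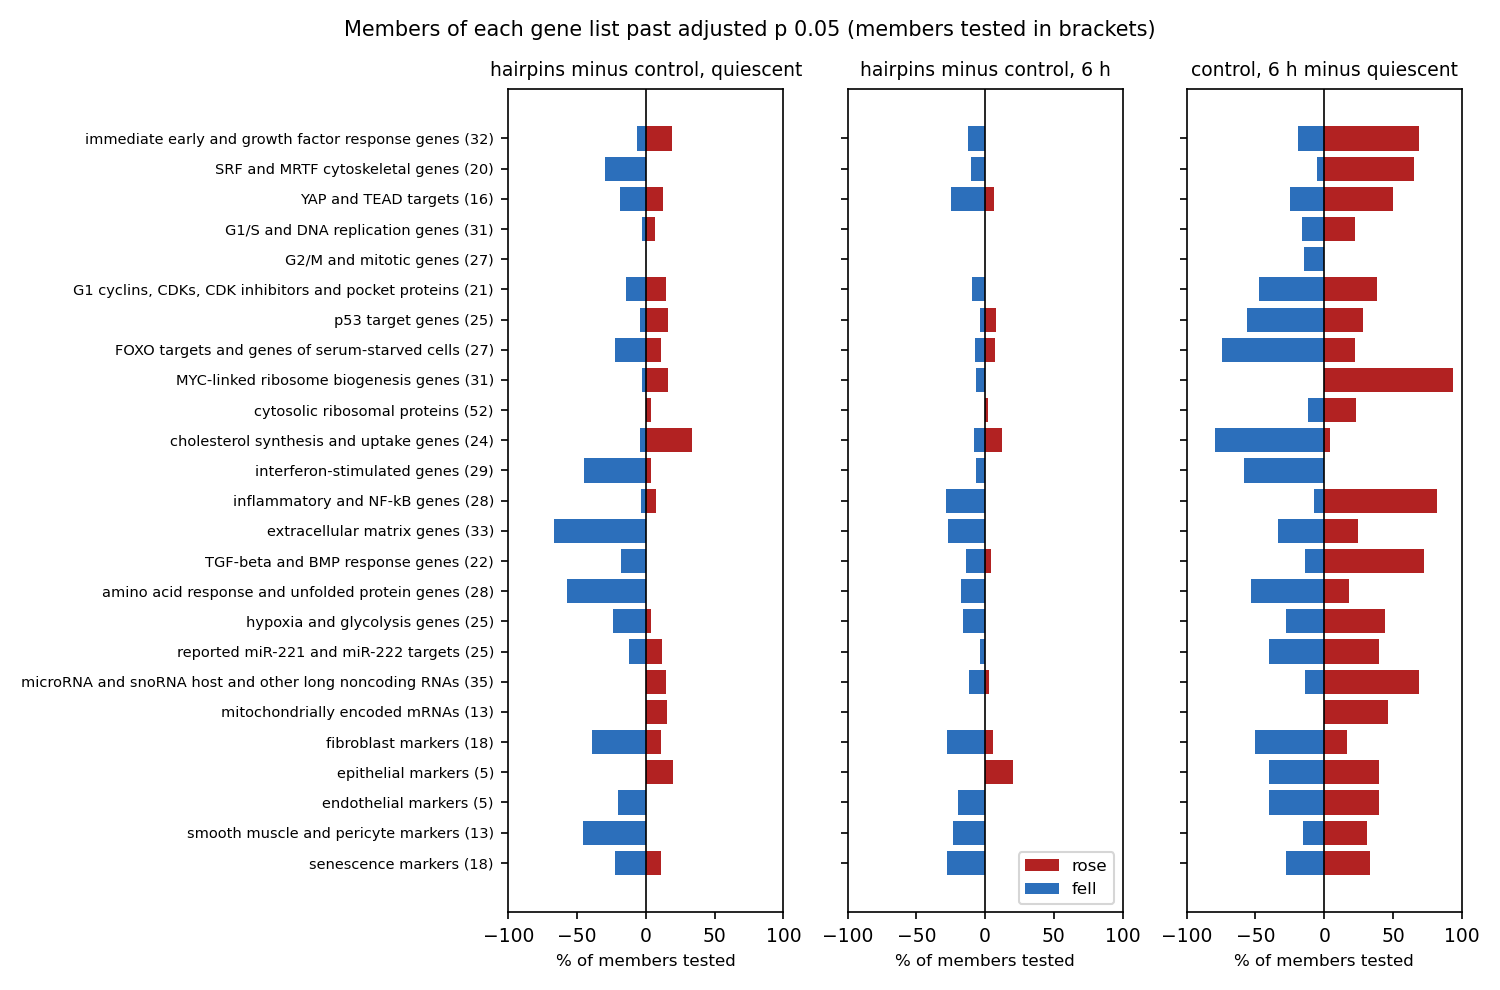
Percent of the tested members of 25 gene lists that rose (right) or fell (left), in 3 panels: hairpins against control in quiescence, hairpins against control at 6 h, and 6 h against quiescence in control. In the quiescent panel 22 of 33 extracellular matrix genes fell, and in the serum panel 29 of 31 ribosome biogenesis genes rose.

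Each hairpin was also compared with control separately, to ask which differences they shared. In quiescence 1268 genes differed with sh1 (539 higher, 729 lower) and 3099 with sh2 (1602 higher, 1497 lower). At 6 h the numbers were 1132 (341 higher, 791 lower) and 1600 (587 higher, 1013 lower). With sh1, ANGPT1, a ligand of the receptor TEK, fell by 1.86 ± 0.15 in quiescence and by 2.67 ± 0.16 at 6 h (adjusted p = 4.8e-06 and 3.46e-07). With sh2 at 6 h, FADS2, a desaturase of fatty acids, fell by 3.48 ± 0.13 (adjusted p = 8.37e-10), from 180 CPM in control to 16.2 CPM. Both hairpins changed 627 genes in the same direction in quiescence, 284 up and 343 down, and 58 in opposite directions, where independent lists would share 127.3. At 6 h they shared 330, 76 up and 254 down, with 38 opposite, where independent lists would share 65.2. The 2 single-hairpin comparisons of a state use the same 2 control libraries, so part of the excess may come from these. Simulated unchanged groups shared at most 1 call in quiescence and 0 at 6 h, but such groups give hardly any calls, so this sets no bound. The correlation of log2 differences between sh1 and sh2 was 0.523 in quiescence, against a mean of 0.488 and a maximum of 0.515 in the simulated groups. At 6 h it was 0.446, below the simulated mean of 0.505. The covariance was 0.138 against 0.0488 in quiescence and 0.118 against 0.0659 at 6 h. Between states no library is shared. There sh1 in quiescence and sh2 at 6 h had 278 changes in common against 68.7 for independent lists, with 75 opposite (r = 0.141 over all genes). For sh2 in quiescence and sh1 at 6 h the numbers were 266 against 112.6, with 141 opposite (r = 0.093). The numbers for independent lists count only changes in the same direction, and none was set beside the opposite ones. Of the genes called in the quiescent comparison, 64.6% and 55.6% had the same sign in the other.

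Single libraries moved these counts by more than 1.5 times. For sh1 in quiescence 596 genes passed without control replicate 1, 648 without sh1 replicate 1 and 471 without sh1 replicate 2. For sh2 the numbers were 1537 without control replicate 1, 1766 without sh2 replicate 1 and 1902 without sh2 replicate 2. At 6 h the sh1 count was 641 and 392 without control replicates 1 and 2 and 630 and 400 without sh1 replicates 1 and 2. The sh2 count was 610 and 881 without control replicates 1 and 2 and 622 without sh2 replicate 1. The shared count in quiescence was 289 without control replicate 1, 311 without sh1 replicate 1 and 277 without sh1 replicate 2. At 6 h it was 156 and 143 without control replicates 1 and 2 and 154 without sh1 replicate 2. Library totals as the only scaling moved the share of genes that were higher from 42.5% to 54.6% for sh1 in quiescence, from 30.1% to 52.8% for sh1 at 6 h and from 36.7% to 58.6% for sh2 at 6 h.

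The hairpin groups differed from each other by more than replicates did. In sh2 against sh1, 2216 genes differed in quiescence (1178 higher in sh2, 1038 lower) and 2498 at 6 h (1241 higher, 1257 lower), while MIR222HG did not (0.08, adjusted p = 0.652, and 0.02, adjusted p = 0.906). VAT1L, lower in sh2, differed by -2.09 ± 0.14 in quiescence (adjusted p = 6.58e-07) and by -3.23 ± 0.17 at 6 h. RGS10, a regulator of G-protein signalling that was lower in sh2 and holds the sh2 word, differed by -1.96 ± 0.09 in quiescence (adjusted p = 2.11e-08). At 6 h FADS2, which holds the sh2 word, differed by -3.23 ± 0.13, and ANGPT1 was higher by 2.40 ± 0.16 (adjusted p = 5.13e-07). Among genes changed in both states 1164 had the same direction against 180.1 for independent lists. The quiescent count was 1374 without sh1 replicate 1, 884 without sh1 replicate 2 and 1090 without sh2 replicate 1, and the 6 h count was 1401 and 1193 without sh1 replicates 1 and 2 and 897 without sh2 replicate 1. Scaling by library totals alone moved the share higher in sh2 in quiescence from 53.2% to 39.9%.

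The serum response of control cells was the largest contrast. CXCL8, a chemokine for neutrophils, rose from 0.77 to 1170 CPM (log2 difference 10.53 ± 0.31, adjusted p = 2.26e-12, n = 2 each). PTGS2, the inducible prostaglandin synthase, rose from 1.14 to 598 CPM (9.02 ± 0.15, adjusted p = 1.11e-14), and SERPINB2, a plasminogen activator inhibitor, from 0.441 to 662 CPM (10.52 ± 0.32, adjusted p = 2.61e-12). The chemokine CCL20 had no read in quiescent control and 784 reads at 6 h, which is at least 365-fold higher against a floor of 3 reads over the group. Among the largest decreases, PTCH1, the Hedgehog receptor, fell from 34.3 to 1.29 CPM (-4.73 ± 0.15, adjusted p = 5.89e-12), and STOX2 from 47.0 to 0.715 CPM (-6.03 ± 0.35, adjusted p = 1.32e-09). The test was passed by 9544 genes, 4861 higher and 4683 lower, and 4338 changed at least 2-fold. Scaling by library totals alone moved the median of all genes from -0.037 to -0.32 and made the split 3392 higher and 6732 lower, 33.5% in place of 50.9% higher, with 201 shared calls changing sign. Directions here are relative to the TMM scaling.

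Growth and inflammatory genes rose with serum. Of 31 ribosome biogenesis genes 29 rose and none fell in any of the 3 tools or unadjusted (29 adjusted over the list alone, camera adjusted p = 5.86e-17, adjusted p = 0.141 with an estimated correlation). The nucleolar protein NOP56 rose by 2.13 ± 0.10 and ODC1 by 4.31 ± 0.13 (57.8 to 1140 CPM). Of 28 inflammatory and NF-kB genes 23 rose and 2 fell (24 and 2 adjusted over the list alone, camera adjusted p = 5.4e-22, adjusted p = 0.00179 with an estimated correlation), IL6 from 4.63 to 157 CPM. Of 32 immediate early and growth factor response genes 22 rose and 6 fell (22 and 6 adjusted over the list alone, camera adjusted p = 8.79e-06, adjusted p = 0.482 with an estimated correlation), HBEGF by 5.25 ± 0.20. Of 22 TGF-beta and BMP response genes 16 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 8.37e-09, adjusted p = 0.141 with an estimated correlation), and INHBA, a subunit of activin, went from 75.3 to 4050 CPM. Of 35 host genes and other long noncoding RNAs 24 rose and 5 fell (24 and 5 adjusted over the list alone, camera adjusted p = 0.00112, adjusted p = 0.478 with an estimated correlation), MIR31HG by 3.98 ± 0.17. SRF and MRTF cytoskeletal genes rose in 13 of 20 cases and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0404, adjusted p = 0.758 with an estimated correlation). The call was lost without quiescent control replicate 2 (0.133) or 6 h control replicate 1 (0.072) and under the stricter filter (0.0896).

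Genes of starved cells fell with serum. Of 27 FOXO targets and genes of serum-starved cells 20 fell and 6 rose (20 and 6 adjusted over the list alone, camera adjusted p = 1.39e-08, adjusted p = 0.012 with an estimated correlation). CCNG2, a cyclin of resting cells, went from 65.5 to 3.56 CPM and SESN3, a brake on mTORC1, from 57.4 to 3.39 CPM. Of 24 cholesterol genes 19 fell and 1, INSIG1, rose (20 and 1 adjusted over the list alone, camera adjusted p = 2.79e-05, adjusted p = 0.141 with an estimated correlation), and HMGCS1, which makes the precursor of mevalonate, fell from 139 to 44.3 CPM. Of 29 interferon-stimulated genes 17 fell and none rose in any of the 3 tools, with 1 higher at an unadjusted p under 0.05 (17 adjusted over the list alone, camera adjusted p = 0.00023, adjusted p = 0.542 with an estimated correlation), with IFIT1 at -3.97 ± 0.24. Among 21 G1 regulators 8 rose and 10 fell (camera adjusted p = 0.338), with the cyclin CCND1 up by 1.35 ± 0.12 and the kinase inhibitor CDKN1B at a log2 difference of -2.11 ± 0.12. Of 27 mitotic genes 4 fell in edgeR (0.31), and of 31 G1/S genes 7 rose and 5 fell (0.811). Of 25 p53 targets 14 fell and 7 rose (camera adjusted p = 0.0891, and 0.0458 without 6 h control replicate 2). Of 28 amino acid response genes 15 fell and 5 rose (0.112, and 0.0338 without quiescent control replicate 2), and of 18 senescence markers 6 rose and 5 fell (0.115, and 0.0445 without 6 h control replicate 1). The remaining lists, among them the matrix genes (8 of 33 up, 11 down) and the miR-221 and miR-222 targets (10 of 25 up, 10 down), were not past the test. Neither were the ribosomal proteins (12 of 52 up, 6 down) and the mitochondrial mRNAs (6 of 13 up), whose calls, such as RPS27A and MT-CO3, were in part lost under library totals. ILF2 rose by 0.92 ± 0.09 and DNM3OS by 0.79 ± 0.15.

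The serum response in the hairpin arms was set against that of control to ask whether it differed. In the sh1 arm 9119 genes changed (4766 up, 4353 down) and in the sh2 arm 7848 (4219 up, 3629 down). Under library totals 34.3% and 37.2% of them rose, in place of 52.3% and 53.8%, and the median of all genes moved to -0.282 and -0.205. Over 3992 genes the slope against control was 0.915 for sh1 (0.858 to 0.983 with single libraries left out) and 0.855 for sh2 (0.800 to 0.932). The receptor IL13RA2, a decoy for interleukin 13, rose from 0.292 to 54.6 CPM in control but from 1.05 to 36.0 CPM in sh1 and from 0.826 to 24.4 CPM in sh2, a difference in log2 response of -2.54 ± 0.26 (adjusted p = 0.000275). HAS2, the hyaluronan synthase, which holds the sh2 word, rose from 4.65 to 747 CPM, from 8.33 to 784 CPM and from 8.16 to 286 CPM (-1.48 ± 0.21, adjusted p = 0.00236). EGR1 differed by -1.28 ± 0.13 and INSIG1 by -1.20 ± 0.14 (adjusted p = 0.000275 and 0.00103). EGR1 fell with serum in control (-1.23), so it fell further in the hairpin arms, while INSIG1 rose in control (2.11). The log2 change of SHISA3, which fell in control (-4.69), was higher by 2.03 ± 0.21 in the hairpin arms, a smaller fall. That of ID3, which rose in control (3.01), was higher by 1.69 ± 0.16, a larger rise (adjusted p = 0.000275 each). A difference in response equals the 6 h difference from control less the quiescent one, so it also holds differences already present in quiescence. SHISA3 and ID3 were already lower, and IL13RA2 already higher, in the quiescent hairpin libraries. GREM1 rose from 1170 to 4990 CPM in control, from 681 to 4510 CPM in sh1 and from 389 to 3480 CPM in sh2 (0.85 ± 0.14, adjusted p = 0.0071). The MIR222HG response differed by -0.80 ± 0.13 (adjusted p = 0.00655; 0.061 without quiescent control replicate 1 and 0.0705 without 6 h control replicate 2).

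**Figure D3:**
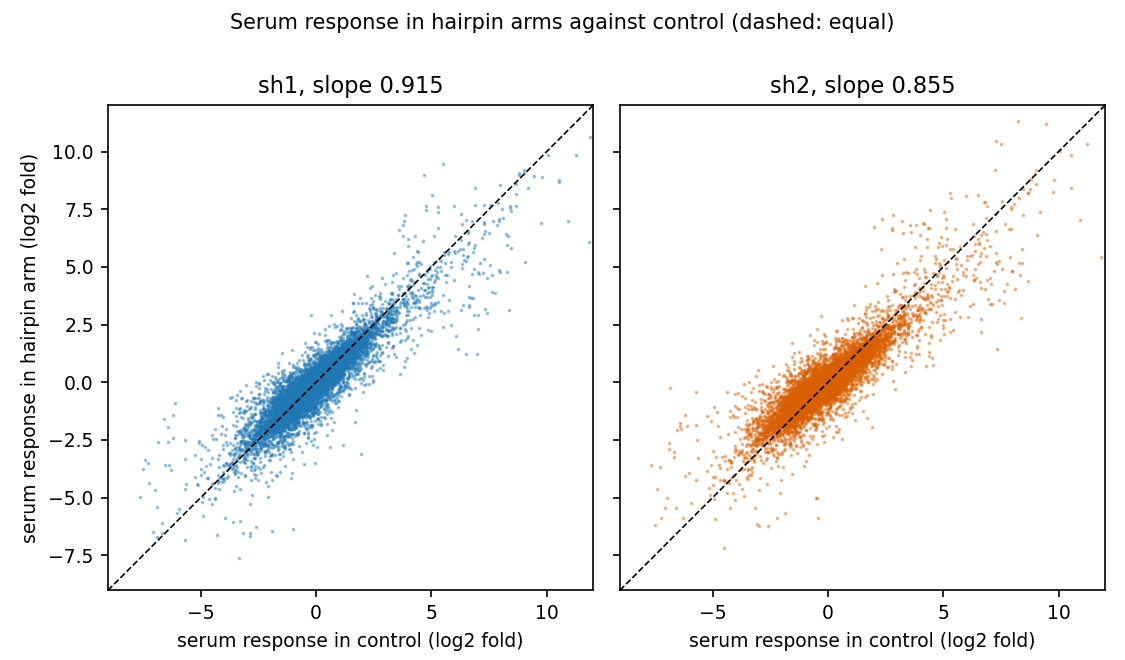
Log2 fold change with serum in the sh1 arm and in the sh2 arm (vertical axes) against that in control (horizontal axes), 1 dot per gene, with the dashed line marking equal responses. The slopes over 3992 genes are 0.915 for sh1 and 0.855 for sh2.

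The response differed in 179 genes, 40 with a higher and 139 with a lower log2 change with serum in the hairpin arms than in control, of which 52 differed by at least 2-fold. A higher change can be a larger rise or a smaller fall. Of the 40, 30 fell with serum in control and 8 rose, and of the 139, 122 rose and 9 fell. The control response is subtracted in the difference, so noise in the control libraries enters both with opposite sign and adds to this split. Leaving out single libraries gave 76 and 84 genes without quiescent control replicates 1 and 2, 72 and 75 without 6 h control replicates 1 and 2, 108 without quiescent sh1 replicate 1, and 119 without sh1 replicate 2 of the 6 h state. Library totals moved the share with a higher change from 22.3% to 38.4%. Of 32 immediate early and growth factor response genes 2 were lower and 1 was higher (6 and 1 adjusted over the list alone, camera adjusted p = 2.41e-06, adjusted p = 0.487 with an estimated correlation). Of 22 TGF-beta and BMP response genes 3 were higher, ID3, ID2 and GREM1 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000694, adjusted p = 0.487 with an estimated correlation). Of 24 cholesterol genes, whose median fell with serum in control, 2 were lower (7 adjusted over the list alone, camera adjusted p = 0.00316, adjusted p = 0.487 with an estimated correlation). Neither of the 2 fell with serum in control: INSIG1 rose (2.11) and STARD4 was not called (0.09). These 3 lists were past the test with every single library left out. A further 7 lists that passed, from the noncoding RNAs to the inflammatory genes, did not hold in every such fit.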

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

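The tests of exchanged labels, of scaling, of a loss of 1 transcript, of repression tied to a word, of GC content and MIR222HG level between the hairpins, and of shared control libraries were chosen only after the result was seen.

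MIR222HG was not lower in the libraries labelled sh1 and sh2, although both hairpins are stated to target it. An exchange of control and hairpin libraries in 1 state only is argued against by a 7-base word of each arm. The 7-base word most tied to lower levels in quiescence (AGGTGTA for sh1, GTTTATC for sh2) was again tied to lower levels in the same arm at 6 h, with z = -10.1 and z = -13.8, whereas the lowest z over permuted genes was -5.1, and such an exchange would turn the sign. An exchange in both states, as a cause for both hairpins, is argued against by the levels of MIR222HG. At 6 h its log2 difference from control was -0.07 in sh1 and -0.04 in sh2, so no exchange of groups gives a lowered one. In quiescence sh2 and sh1 differed by 0.08, so an exchange of control with 1 of them leaves the other not lower. The words do not decide whether labels were exchanged in both states. In the other arm at 6 h the sh1 word had z = 1.2 and the sh2 word z = 1.1, but a control hairpin may have a word of its own, and no hairpin sequence is given. Scaling is argued against in quiescence, because a wrong factor moves all genes of a library alike and MIR222HG lay 0.76 above the median gene, relative to the transcripts tested. At 6 h it lay at -0.06 from the median gene, within its error, which decides nothing. Each word also occurs in 1 of the 2 annotated MIR222HG transcripts, both in its exon 2 on chromosome X, from 45745955 to 45745961 for sh1 and from 45746076 to 45746082 for sh2 (GRCh38). Whether the guides match MIR222HG cannot be told from this, since the words were found from expression and the hairpin sequences are not given. A word in at least 1 transcript had been set in advance as the bound against guides without a match, which was wrong for that reason. By chance a given word would lie in this transcript of 1379 bases in 7.8% of cases and both words in 0.61%, and in the other, of 1758 bases, in 9.6% and 0.92%. The transcript was not chosen beforehand, so the chance of a find in either is higher than each of these. A loss of only the 1 transcript that holds both words, or of RNA in 1 compartment of the cell, may remain hidden in gene counts that do not separate exons, and these stay open together with hairpins that did not lower the RNA.

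The hairpin groups differed from each other in 2216 genes in quiescence and 2498 at 6 h, by a direct test between them. With the sh1 word in the 3' untranslated region, 19% of genes were lower in sh1 at 6 h against 4.9% without it, and with the sh2 word 21.2% were lower in sh2 against 6.1%. The medians of the genes with the word were -0.12 for sh1 and -0.10 for sh2, in libraries that share none with those in which the words were found, which is in line with repression of many transcripts through a site tied to each arm. The other arm showed less of this: at 6 h 8.9% of genes with the sh2 word were lower in sh1 against 5.7% without it, and 8.5% of genes with the sh1 word were lower in sh2 against 7.5%. In quiescence these values were 7.1% against 5.4% and 10.8% against 11.1%. Whether that site is the seed of the hairpin was not checked, because the sequences are not given. The effect covers only part of the pattern, since 205 of 766 genes called lower in sh1 and 266 of 963 in sh2 hold the arm's word. Transcript GC content as the whole cause is argued against by 1918 of the 2498 genes that were still called after a GC correction. A trend with GC content was present, with rank correlations of -0.176 in quiescence and -0.359 at 6 h. After the correction 2657 genes in all were called at 6 h. A different MIR222HG level, counted over the whole gene, is argued against by log2 differences between the hairpins of 0.08 in quiescence and 0.02 at 6 h. These gene counts do not separate exons. An unequal loss of only the transcript that holds both words, or of RNA in a single compartment of the cell, therefore stays open. What underlies the rest was not tested, and differences between the infected cultures stay open.

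Quiescent hairpin libraries were weakly shifted toward the serum response, sh1 less than sh2. Across genes, the quiescent difference of sh1 from control correlated with the serum response measured in sh2 at r = 0.163, and that of sh2 with the response in sh1 at r = 0.234, where genes are not independent replicates. Neither pair shares a library, so noise common to both terms of a pair is argued against. Among genes called in both terms of a pair, 526 had the same sign and 342 the opposite for sh1, and 1714 and 586 for sh2. With the 6 h differences in place of the quiescent ones, r was -0.043 for sh1 and -0.117 for sh2. Both quiescent differences use the same 2 control libraries, so control cultures that themselves lay off along the serum response stay open. After a GC correction the values were 0.157 and 0.237, which argues against GC content as the whole cause. Material carried over from serum-treated cells is argued against by 136 transcripts that serum raised at least 16-fold in control. Their median excess in the quiescent hairpin groups was 0.413% of the 6 h level in sh1 and 0.287% in sh2. Genes called higher both in that hairpin group and with serum had a median excess of 36.4% and 38.9% of their serum rise. That choice favours large shares, and these are shares of the rise and not of the 6 h level. Some lists went against the shift: 8 of 24 cholesterol genes rose in the quiescent hairpin libraries but 19 fell with serum in control, 4 of 22 TGF-beta genes fell but 16 rose with serum, and 6 of 20 SRF and MRTF genes fell but 13 rose. Others went with it: 13 of 29 interferon-stimulated genes fell and 17 fell with serum, 5 of 31 ribosome biogenesis genes rose and 29 rose, and 5 of 35 noncoding RNAs rose and 24 rose. The quiescent calls of the SRF, ribosome biogenesis and noncoding RNA lists were each lost without 1 of the quiescent control libraries. The FOXO targets were not past the test in quiescence (camera adjusted p = 0.787). A shallower quiescence of these cells was not tested. Separate handling of the cultures, such as cell density, was not tested either and stays open, while the labels give 3 days in low serum for every library.

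The serum response differed between the hairpin arms and control in 179 genes, tested as an interaction. Here higher and lower refer to the log2 change with serum in the hairpin arms less that in control, so a higher value can be a larger rise or a smaller fall. A difference from control already present in quiescence enters this value with the opposite sign. Higher values were those of SHISA3 (2.03), ID3 (1.69), FAM20C (1.51) and CRISPLD2 (1.21), which were past the test with every single library left out. Those of DEPP1 (2.01), ADAMTS14 (1.60), PTHLH (1.47), S1PR1 (1.46) and FLRT2 (1.18) were lost in 5 or more such fits, among them some without a control library. That of SETBP1 (1.30) was lost without 6 h control replicate 1. SHISA3, DEPP1, FAM20C, ADAMTS14, S1PR1 and SETBP1 fell with serum in control, so these were smaller falls, and FLRT2 fell in control as well (-0.96). Lower values that held in every such fit were those of IL13RA2 (-2.54), SLC14A1 (-1.75) and HAS2 (-1.48). Those of NPTX1 (-1.97), SIGLEC15 (-1.77) and FRK (-1.51) were lost in 5 or 6 such fits, with adjusted p of up to 0.145, 0.115 and 0.137. RGS4 (-1.63) was lost without quiescent control replicate 2 (0.108) and either 6 h control replicate (0.0575 and 0.062), MMP1 (-1.61) without quiescent control replicate 1 (0.106) or 6 h control replicate 2 (0.0919), and MKX (-1.60) without 6 h control replicate 1 (0.055). EDN1 (-1.47) was lost without either quiescent control replicate (0.0832 and 0.0533) or 6 h control replicate 1 (0.0508). MIR222HG itself differed by -0.80, where the hairpin groups were at 0.75 from control in quiescence and at -0.06 at 6 h. IL13RA2 and SLC14A1 were already higher in the quiescent hairpin libraries, and the 6 h level of HAS2 was not lower in sh1 than in control. S1PR1 and SLC14A1 hold the sh1 word, PTHLH, FLRT2 and HAS2 the sh2 word, and FRK both.

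In the same interaction 10 gene lists were past camera's test, 3 toward a higher and 7 toward a lower log2 change in the hairpin arms, and none with an estimated correlation. Immediate early, TGF-beta and cholesterol genes held with every library left out. The noncoding RNAs (3 of 35 lower, camera adjusted p = 0.00255, adjusted p = 0.487 with an estimated correlation) were lost without quiescent control replicate 1 (0.138). Mitochondrial mRNAs (0.00933, no member past the test in edgeR, DESeq2 or limma-voom and 1 lower at an unadjusted p under 0.05) were lost without quiescent control replicate 1 (0.138), 6 h control replicate 2 (0.0843) or 6 h sh2 replicate 1 (0.0568). Ribosome biogenesis genes (0.0124, no member past the test over all genes in edgeR or limma-voom, 3 lower in DESeq2 and 10 lower at an unadjusted p under 0.05) were lost without quiescent control replicate 2 (0.349), quiescent sh2 replicate 1 (0.0579) or 6 h sh2 replicate 1 (0.0766). For both of these lists, and for amino acid response genes, adjusted p = 0.853 with an estimated correlation. Of 28 amino acid response genes 0 were higher and 1, DNAJB9, was lower in edgeR (1 and 1 adjusted over the list alone). Of 33 matrix genes 0 passed in edgeR (0 higher and 1 lower adjusted over the list alone). The amino acid response genes (0.0153, higher) were at 0.488 without quiescent control replicate 1, the matrix genes (0.0208, higher, adjusted p = 0.963 with an estimated correlation) at 0.852, and the inflammatory genes (0.0432, lower) at 0.066. The senescence markers (0.0408, lower) were at 0.139 without 6 h control replicate 2, and for them and the inflammatory genes adjusted p = 0.487 with an estimated correlation.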

How the results depend on the processing

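For the counts, genes and lists given here, the GC correction was chosen only after the result was seen. Of 386 results for named genes, 255 kept direction and call in every alternative. Among their 8064 values under the alternatives, 7579 did so, 473 kept the direction but lost the call and 12 reversed. The reversals were 11 values of MIR222HG and MT-CO3 in the serum response with library totals (-0.01), none past the test. Those of MIR222HG were the hairpins at 6 h with library totals (0.02) and without 6 h control replicate 2 (0.04), sh1 at 6 h with GC correction (0.03) and without that library (0.02), and sh2 at 6 h with library totals (0.04), without that library (0.06) and without sh2 replicate 2 (0.04). Between hairpins they were -0.01 in quiescence without sh2 replicate 2, and at 6 h -0.14 with GC correction, -0.01 without sh1 replicate 2 and -0.04 without sh2 replicate 1. The MIR222HG rise with serum in sh2 was also not past the test with no low-count filter, the stricter filter, DESeq2, GC correction or only the groups compared (adjusted p = 0.0966, 0.0512, 0.0763, 0.195 and 0.114). With single libraries left out MIR222HG ran from -0.12 to 0.04 at 6 h, from -0.14 to 0.02 for sh1 and -0.11 to 0.06 for sh2 at 6 h, from -0.01 to 0.17 and -0.04 to 0.10 between hairpins, and from -0.88 to -0.70 for the interaction, where its call was lost without quiescent control replicate 1 or 6 h control replicate 2. With a block for the replicate number, by which no label pairs the cultures (correlations of replicate differences were over 0.1 in 11 of 15 pairs of groups and ran from -0.021 to 0.254), more genes passed: 1722 for the hairpins at 6 h, 526 for the interaction, 2096 and 1880 for sh1 in quiescence and at 6 h, and 1087 and 559 changed by both hairpins in quiescence and at 6 h. GC correction gave 1697 genes for the hairpins at 6 h, 311 for the interaction, 526 for both hairpins at 6 h, and 6 lists for the interaction, and the cause was not tested. Without it, rank correlations of log2 differences with GC content were -0.254 for the hairpins in quiescence and 0.08 at 6 h. They were -0.168 for the serum response in control and 0.294 for the interaction. The interaction count was 584 with no low-count filter and 379 with DESeq2, and the cause was not tested. Counts stayed within 1.5 times under size factors, library totals, the stricter filter, limma-voom and the groups compared alone, the last of which cannot differ for the interaction. With single libraries left out, where fewer samples carry the test, the counts ran from 803 to 2391 for the hairpins in quiescence, 420 to 1108 at 6 h, 72 to 186 for the interaction, 471 to 1455 and 392 to 1255 for sh1 in quiescence and at 6 h, 1537 to 3315 and 610 to 1622 for sh2, 884 to 2395 and 897 to 2627 between hairpins, and 277 to 731 and 143 to 332 for both hairpins. Lists past the test ran from 8 (without 6 h control replicate 1) to 14 for the hairpins at 6 h, and from 6 (without quiescent control replicate 1 or 6 h sh2 replicate 1) to 11 for the interaction. With an estimated correlation 0, 1, 2 and 0 lists passed in the main comparisons, and with the block as well 0, 0, 2 and 0, since the inflammatory and NF-kB genes at 6 h were then at 0.0516. The slope was 0.955 for sh1 and 0.896 for sh2 over genes called in the hairpin arm and 0.863 and 0.801 by least squares, and ran from 0.858 to 0.983 and from 0.800 to 0.932 with single libraries left out. Depth limits the genes with no reads in a group, for which only bounds can be given.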

Other observations

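The overlap of genes without either word was planned before its result was seen, and the test of a word shared by both hairpins was chosen only after the result was seen.

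Genes that hold an arm's word and were lower in both states with that hairpin were chosen after their values were seen. There were 135 of them for sh1, among them the matrix protease ADAMTS5 (-1.83 in quiescence and -1.64 at 6 h), the growth factor TGFB2 (-1.36 and -1.40) and the apoptosis modulator MOAP1 (-1.46 and -1.42). For sh2 there were 179, among them the secreted protein EGFL6 (-3.11 and -4.48), the ligand BMP5 (-2.27 and -3.94), the flavin monooxygenase FMO2 (-1.67 and -2.74) and the microfibril protein MFAP4 (-2.13 and -1.94). Among all genes with an annotated 3' untranslated region, 2119 of 12646 (16.8%) hold at least 1 of the words. Of the 10 largest decreases named for the hairpins against control at 6 h, 4 hold 1, and of the 10 in quiescence 2 do.

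The genes lower with both hairpins could be those that hold the words of both arms. Without the genes that hold either word, 173 genes were lower with both hairpins at 6 h. Independent lists would give 30.2, a ratio of 5.73. Lower calls with both hairpins were thus not confined to genes with a word in the region searched. In quiescence the numbers were 251 and 48.3. These comparisons share the control libraries of a state, which adds to the overlap. Across states no library is shared. Over all genes, word holders included, sh1 in quiescence and sh2 at 6 h shared 206 lower genes against 48.1. For sh2 in quiescence and sh1 at 6 h the numbers were 205 against 77.1. In these pairs 75 and 141 genes changed in opposite directions.

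Another word, CTGGTTC, went with lower levels in both arms. It was picked in quiescence (z = -6.2 in sh1 and -5.8 in sh2), and at 6 h its z was -4.1 in sh1 and -7.0 in sh2, so only the sh2 value lay beyond the lowest permuted z of -5.1. Whether a shared sequence acts on these transcripts cannot be told apart from a trend in the shared control libraries, and the word may mark neither.

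In the comparisons of single hairpins and arms, the remaining extremes were as follows. SERPINB7 was higher with sh2 by 3.83 ± 0.22 in quiescence and by 2.82 ± 0.20 at 6 h. Integrin ITGA10 was higher with sh1 by 1.96 ± 0.15 in quiescence. The keratin-associated protein gene KRTAP1-5 was higher in sh2 than in sh1 by 2.27 ± 0.29 in quiescence (adjusted p = 0.000142). Reads shared among near-identical members of its family leave this count uncertain.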
